A study of Homo sapiens with 3 samples.

How the data were processed

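Droplet libraries (10x Genomics Chromium, 3′ end) were measured for 3 groups with 1 library each: monoculture DMSO, coculture DMSO and coculture niclosamide. Each library held PaTu-8902 tumour cells and HUVECs. The deposited files hold raw UMI counts per Ensembl gene and cell barcode, without normalization. Every value was a whole number. Per the submitters' processing notes the authors used Cell Ranger, with no version given, against hg38; the annotation release and the settings for calling cells were not stated. The files listed 33694 genes, of which 32807 were matched to a symbol through their Ensembl identifier; positions, transcript lengths and snoRNA hosts came from GENCODE 29 (GRCh38). Of 913 gene list entries 912 were found; SOD2 was not.

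Cells with at least 500 genes detected and at most 20% mitochondrial UMIs were kept, which removed 5, 11 and 1 barcodes and left 6580, 5695 and 4477. Counts were scaled to 10000 UMIs per cell and log-transformed. All libraries were clustered together on 2000 variable genes and 30 principal components, with 20 neighbours and Leiden resolution 0.5, without batch correction. Scrublet called 134, 95 and 63 doublets (2.04%, 1.67% and 1.41%). A cluster was endothelial-like when the median tumour share of marker UMIs was under 35% and tumour-like when it was over 70%, from 18 endothelial and 20 epithelial markers. Clusters in which over 50% of barcodes were doublet calls, or which were led by markers of another class, were not named. Doublets and unnamed clusters, 235, 166 and 81 barcodes, were left out of the classes. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

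UMIs were summed over the cells of a class in each library (97333201, 90162778 and 106368987 in tumour-like, 53015653, 50517703 and 37476188 in endothelial-like cells) and given as CPM, counts relative to the class total. Each of 4 comparisons took the ratio of CPM of a pair of libraries, with an exact conditional binomial 95% interval. That interval reflects counting error alone, not variation between cultures or library preparations. A gene was measured with at least 50 UMIs and 20 CPM in the higher library. The level of other-class RNA was estimated per library as the median, over the other class's markers, of their CPM in this class relative to their own class. A gene was left out where this level times its CPM in the other class came to over 25% of its CPM in either library, which removed 156, 847, 184 and 1269 genes from coculture in tumour-like and endothelial-like and from niclosamide in tumour-like and endothelial-like cells. A library at 0 UMIs was set to 3 UMIs. Genes at or above 2-fold were counted by size; no test across samples was possible. The median log2 ratio of all genes compared was −0.01, −0.04, 0.06 and 0.05.

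For 39 gene lists, the median log2 ratio of compared members was placed among 10000 random lists of the same size matched on level in 20 bins; lists with fewer than 3 compared members got no percentile. Chance alone would put about 5% of lists outside the central 95%, and list members are not independent. Genes named were, per class and comparison, the 12 highest and 12 lowest by the interval bound nearest to no change among protein-coding genes at or above 2-fold, without mitochondrially encoded and cytosolic ribosomal protein genes and Y-linked genes, and up to 4 members of each list described. Relations between comparisons were Pearson correlations across genes, and those sharing a library were set against 100 simulated runs of unchanged libraries and against a split of the shared library.

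The comparison was tested on simulated data with 50 genes at each of 4 known folds per comparison. The simulated counts held counting error alone, without variation between cultures or libraries and without other-class RNA. Changed genes were drawn only from genes well above the CPM minimum. The results below therefore check the calculation and say nothing about false calls between real cultures. All 50 genes at 2.5, 4 and 8-fold were called at or above 2-fold, 0 of 50 at 1.5-fold were, and no unchanged gene was. Intervals held the true ratio for 95.4%, 95.2%, 95.7% and 95.5% of genes, and 1, 1, 2 and 0 of 40 lists of unchanged genes lay outside the central 95%.

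The groups, comparisons, lists, rules for named genes and most alternatives were chosen before the data were examined. Alternatives were scaling to the median ratio, equal weight per cell, cells thinned to 8000 UMIs, stricter and looser gene and cell filters, doublets kept, classes by marker UMIs, other-class genes kept or other-class RNA subtracted, cells with low cell cycle scores, and thresholds of 1.5-fold and 3-fold. Those chosen after seeing the data were other-class RNA subtracted for named genes and lists, barcodes with mixed markers left out, the tumour clusters with high interferon genes or high mitochondrial share left out, an unnamed cluster counted as endothelial, and thinned cells for lists. Y-linked genes and XIST were left out of all tables.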

Results

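The deposited data were counts from 3 droplet libraries (10x Genomics Chromium, 3′ end counting) of PaTu-8902 cells, a human pancreatic ductal adenocarcinoma line, and human umbilical vein endothelial cells (HUVECs). The series concerns drugs that hold back the passage of tumour cells through the endothelium. The 3 groups had 1 library each: monoculture with the solvent DMSO, coculture of tumour cells on an endothelial monolayer with DMSO, and coculture with niclosamide. Per the labels, cultures held 375000 PaTu-8902 cells and 200000 HUVECs, niclosamide was used at 1.0 µM, and 5200 cells were loaded per library after isolation at 8 h. Niclosamide is an anthelmintic that uncouples mitochondrial respiration from ATP synthesis. The labels do not say how the separately grown cells of the monoculture library were brought together, or from which step the 8 h were counted. The monoculture library held 6585 barcodes and 159029750 UMIs, the coculture DMSO library 5706 barcodes and 146542165 UMIs, and the niclosamide library 4478 barcodes and 147477260 UMIs. Both DMSO libraries thus held more barcodes than the 5200 cells that the labels give as loaded. The median barcode had 20501, 22505 and 29438.5 UMIs in the same order. With 1 library per group, no difference could be set against a spread between replicates, so no test was run, and all intervals cover counting error only.

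Each library separated into tumour-like cells, with epithelial genes such as KRT19 and EPCAM, and endothelial-like cells, with VWF, PECAM1 and CDH5. KRT19, a keratin of simple epithelia, stood at 1929 CPM in tumour-like and 314 CPM in endothelial-like cells of the monoculture library. PECAM1, an adhesion molecule of endothelial contacts, stood at 27.5 CPM and 282 CPM in these cells. Tumour-like cells made up 2681 of 6345 classified cells (42.3%, exact Clopper-Pearson 95% interval 41.0 to 43.5) in monoculture and 2428 of 5529 (43.9%, 42.6 to 45.2) in coculture with DMSO. With niclosamide they made up 2134 of 4396 (48.5%, 47.06 to 50.03). The lowest barcode of each library held 6913, 7162 and 8298 UMIs, close to 0.1 times the 99th percentile (6639, 7127 and 8302 UMIs), and 32.7%, 24.5% and 36.9% of endothelial-like cells lay within 1.5 times this lowest value. Among tumour-like cells the same figure was 1.1%, 1.2% and 1.2%, so a higher limit on UMIs would remove mainly endothelial-like cells. Barcodes under the lowest value were not in the data, so the effect of a lower limit could not be seen, and no other UMI limit was tried. RNA of the other class was present in every library: tumour markers in endothelial-like cells stood at 14.6%, 16.6% and 18.4% of their level in tumour-like cells, and endothelial markers in tumour-like cells at 8.73%, 9.62% and 8.91%. Classes were also set by marker UMIs in place of clusters, with at least 90% of a barcode's marker UMIs from the class. This left 29 endothelial-like cells in the niclosamide library, whose tumour-like share was then 98.4%. The endothelial cluster of that library had a median tumour share of marker UMIs of 26.5%, so the rule dropped most of its cells by construction. Tumour-like cells had a median of 34434, 35324 and 48323 UMIs and a median mitochondrial share of 4.05%, 4.32% and 2.84%. Endothelial-like cells had 12561, 14484 and 14521.5 UMIs and 3.27%, 3.31% and 2.97%.

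The comparison of the DMSO libraries asks how endothelial and tumour cells differ when they are cultured together rather than apart. In endothelial-like cells, inflammatory genes stood far higher in coculture. CXCL1 (ENSG00000163739; GRCh38 chromosome 4, 73869393 to 73871242), which encodes a chemokine that attracts neutrophils, was 10.3-fold higher, at 194 against 18.9 CPM (log2 ratio 3.36, 95% interval 3.27 to 3.46). ICAM1 (ENSG00000090339; chromosome 19, 10270835 to 10286615), the endothelial receptor for leukocyte integrins, was 9.77-fold higher, at 42.0 against 4.30 CPM (3.29, 3.09 to 3.49). The monocyte attractant CCL2 (ENSG00000108691; chromosome 17, 34255218 to 34257203) stood at 897 against 162 CPM (2.47, 2.43 to 2.5). The chemokine genes CXCL2 and CXCL8 had log2 ratios of 3.19 (3.04 to 3.33) and 2.41 (2.28 to 2.54). RELB, a subunit of the transcription factor NF-kB, stood at 23.4 against 6.36 CPM (1.88, 1.70 to 2.06), TNFSF10, the death ligand TRAIL, at 44.5 against 17.1 CPM (1.38), and the cytokine gene IL32 at 231 against 107 CPM (1.11). Of the NF-kB inflammatory targets, all 7 compared members were higher and 6 were at least 2-fold higher; the list median of 2.47 lay at percentile 100 of random lists matched on level. These 8 genes were all that reached 2-fold higher among the 3547 genes compared, against 26 at least 2-fold lower.

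**Figure D1:**
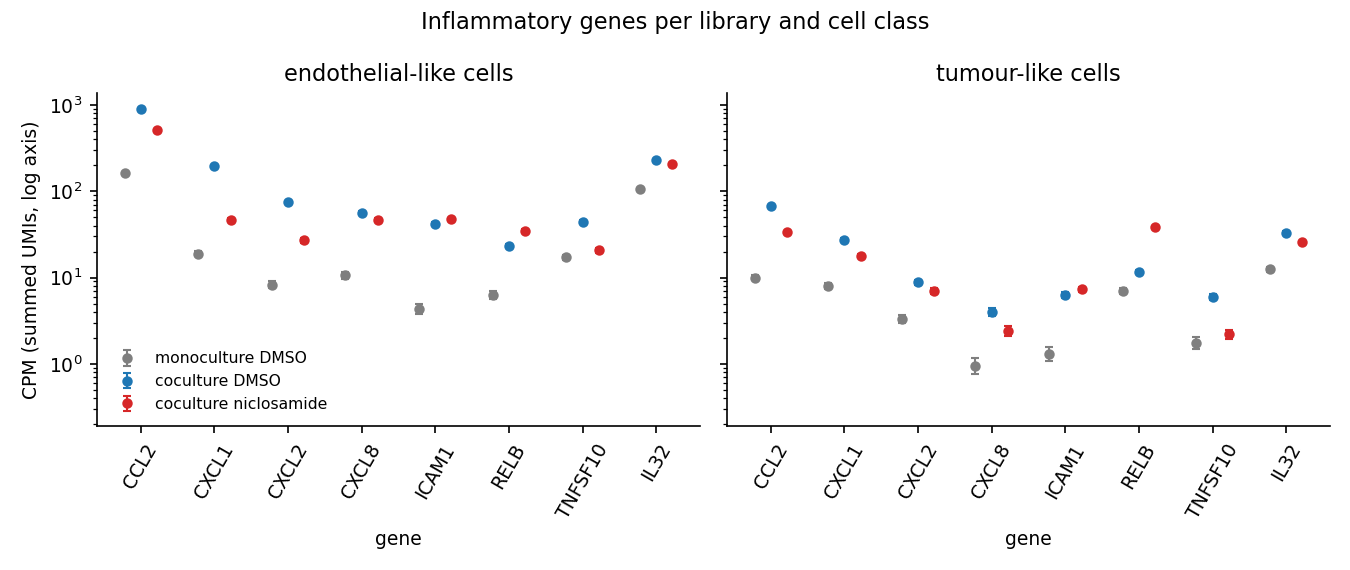
Level in CPM (log axis) of the 8 genes at least 2-fold higher in endothelial-like cells of the coculture, per library (colour) in endothelial-like (left) and tumour-like cells (right); points are 1 library each and bars are 95% counting intervals. In endothelial-like cells CXCL1 stood at 18.9, 194 and 46.7 CPM and ICAM1 at 4.30, 42.0 and 47.3 CPM in the monoculture, coculture DMSO and niclosamide libraries. In tumour-like cells CCL2 (66.8 CPM in coculture DMSO, 10.0 in monoculture) and CXCL1 (27.3 and 8.0 CPM) were left out of the comparison. Endothelial RNA could give 142.2% and 68.5% of their level there.

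Genes of adhesion, matrix and mechanical signalling stood lower in the endothelial-like cells of the coculture. All 17 compared members of the basement membrane and matrix list were lower (median −0.34, percentile 0), among them the multimerin gene MMRN1 (−0.75), THBS1, which encodes thrombospondin (−0.63), and the collagen gene COL4A2 (−0.51). Of the YAP/TEAD targets, which respond to cell shape and tension, 9 of 10 were lower (median −0.43, percentile 0.01), led by ANKRD1 at 254 against 582 CPM (−1.19, −1.22 to −1.17), CRIM1 (−0.75) and CCN2 (−0.60). Integrins were lower in 5 of 6 members (median −0.42, percentile 0.44; ITGB1 −0.70, ITGA5 −0.48). Among the endothelial junction genes 11 of 12 were lower (median −0.26, percentile 0.75, but 2.77 and thus inside the central 95% with random lists matched on transcript length as well), including CDH5 (VE-cadherin, −0.46) and CTNNB1 (beta-catenin, −0.49), while the tight junction gene CLDN5 was higher (0.69). Flow and quiescence genes were lower in 9 of 10 members (median −0.31, percentile 0.07; TIE1 −0.44, KLF2 −0.46), and extracellular proteases and inhibitors in 10 of 13 (median −0.26, percentile 0.64; TIMP2 −0.71, MMP14 −0.40). TGF-beta targets were lower in 9 of 10 members (median −0.36, percentile 0.09; CCN2 −0.60, COL4A2 −0.51), epithelial-mesenchymal transition genes in 7 of 9 (median −0.29, percentile 0.49; CDH2 −0.67, AXL −0.44), Wnt/beta-catenin targets in 3 of 5 (median −0.31, percentile 1.91; BMP4 −0.48, DKK1 −0.34), and actin and contractility genes in 20 of 30 (median −0.10, percentile 0.75; RND3 −0.53, VCL −0.51, against TAGLN at 0.48). Interferon-stimulated genes were higher in 4 of 5 members (median 0.24, percentile 99.4; IFI27 0.44, ISG15 0.33), and p53 targets were higher in 8 of 11 (median 0.16, percentile 99.7; BBC3 0.37, BAX 0.26). The other named genes that stood lower included NMT2, an N-myristoyltransferase (−1.58, −1.65 to −1.51), HES1, a Notch target (−1.18), the translation factor subunit EIF3J (−1.34), the deubiquitinase-family gene USP53 (−1.31), the cochaperone DNAJB4 (−1.11) and TCEAL9 (−1.11). Log2 ratios in endothelial-like cells were lower for genes with longer transcripts (Spearman rho across 3547 genes −0.41; genes are not independent replicates), with a median of 0.08 in the 20% of genes with the shortest and −0.19 in the 20% with the longest transcripts. In tumour-like cells of the same libraries rho was −0.18, with medians of 0.02 and −0.06. A cluster with higher MKI67 (151 CPM against 23.5 to 27.0 CPM in the other endothelial clusters) held 1106 of 3677 endothelial-like cells in monoculture and 669 of 3105 in coculture, doublet calls counted, and no replicate showed how far such ratios vary between libraries.

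In tumour-like cells fewer genes reached 2-fold between the same libraries with the main gene filter. With the looser gene filter more did, 113 higher and 270 lower against 103 and 197 in endothelial-like cells. Without batch correction, cells of the DMSO libraries lay largely in different clusters in both classes: the largest tumour clusters held 2535 monoculture and 10 coculture cells, and 11 and 2320, and the largest endothelial clusters 2470 and 33, and 97 and 2393. ID3 (ENSG00000117318; chromosome 1, 23557918 to 23559794), an inhibitor of basic helix-loop-helix factors and a target of BMP signalling, was 2.55-fold higher in coculture, at 429 against 168 CPM (log2 ratio 1.35, 1.32 to 1.38). JUNB (ENSG00000171223; chromosome 19, 12791496 to 12793315), an AP-1 transcription factor, was 2.08-fold higher, at 141 against 67.9 CPM (1.06, 1.01 to 1.10). These 2 genes were the only ones of 4095 to reach 2-fold higher, and 24 stood at least 2-fold lower. Among the lower genes were NMT1, the other N-myristoyltransferase of human cells, at 66.8 against 242 CPM (−1.86, −1.90 to −1.82), APOLD1 (−1.71), EIF3J (−1.40), the adhesion receptor ADGRF1 (−1.35), the imprinted gene PEG10 (−1.25), WDR70 (−1.26), CWF19L2 (−1.18), the threonyl-tRNA synthetase TARS1 (−1.11) and the nucleolar protein gene WDR43 (−1.06). Genes of ATP synthase and of the respiratory chain and its assembly were also in this group: ATP5ME (−1.18), COX16 (−1.20) and NDUFB1 (−1.08).

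Of the 33 lists with at least 3 compared members in tumour-like cells, 9 lay outside the central 95% of random lists, most with small medians. Heat shock genes were lower in 10 of 11 members (median −0.22, percentile 0.14), led by HSPA1A (−0.61), whose near-identical copy HSPA1B can share its reads, and HSP90AB1 (−0.36). Unfolded protein response genes were lower in 11 of 12 (median −0.12, percentile 1.86), including the chaperone HSPA5 (−0.42) and PDIA4 (−0.40). Cell cycle genes were lower in 21 of 24 members for G1/S (median −0.11, percentile 0.94; ATAD2 −0.29, PCNA −0.21) and in 31 of 42 for G2/M (median −0.09, percentile 0.25; TOP2A −1.02, CDK1 −0.55). Nuclear-encoded respiratory chain genes were lower in 31 of 44 (median −0.04, percentile 1.64; NDUFA1 −0.70, COX7C −0.42), and metallothioneins in 3 of 4 (median −0.31, percentile 0.94; MT1X −0.48, MT1E −0.39). TGF-beta targets were higher in all 3 compared members (median 0.59, percentile 100; SKIL 0.73, PMEPA1 0.59). The basement membrane list was higher in 3 of 4 (median 0.30, percentile 99.9), including the laminin chains LAMB3 (0.67) and LAMA3 (0.39), with LAMA5 at −0.19. Interferon-stimulated genes were higher in all 3 (median 0.25, percentile 99.3; ISG20 0.32, ISG15 0.25). A small tumour-like cluster led by such genes, ISG15 among them, held 41 cells in monoculture and 45 in coculture, doublet calls counted. No list median was taken without this cluster, so its part in the interferon median is not known. In cells with low cell cycle scores the interferon median was −0.01, so its direction was not kept there. A tumour cluster with a high mitochondrial share (median 10.6%) held 76 cells in monoculture and 37 in coculture, doublet calls counted. HSPA1A was among the leading genes of this cluster, and the HSPA1A ratio without the cluster was not taken. List medians moved by at most 0.1 without it.

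Coculture ratios were also set against each other across the cell classes. Across the 2493 genes compared in both, tumour-like and endothelial-like log2 ratios had a Pearson r of 0.83, where genes are not independent replicates; it was 1 of 4 such relations computed. Both classes came from the same 2 libraries and held RNA of each other (8.73% to 16.6% of marker levels), which by itself gives a positive relation, and no value without change was simulated for it. In both classes 10 genes stood at least 2-fold lower in coculture, where unrelated classes would give 0.1. The 0 genes that were 2-fold in opposite directions say little, since so few reached 2-fold that unrelated classes would give 0.0. The 10 lower genes were EIF3J, ATP5ME, NDUFB1, COX16, WDR70, UQCC5 and, chosen after their values were seen, the ribosomal protein gene RPS29 and the noncoding genes SNHG9, SNHG25 and MIR4458HG. EIF3J stood at 440, 166 and 170 CPM in tumour-like cells and at 318, 125 and 103 CPM in endothelial-like cells of the monoculture, coculture DMSO and niclosamide libraries. ATP5ME stood at 1115, 492 and 273 CPM and at 908, 427 and 334 CPM. As no group had a second library, a difference between the libraries as a whole and one between culture forms cannot be told apart.

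**Figure D2:**
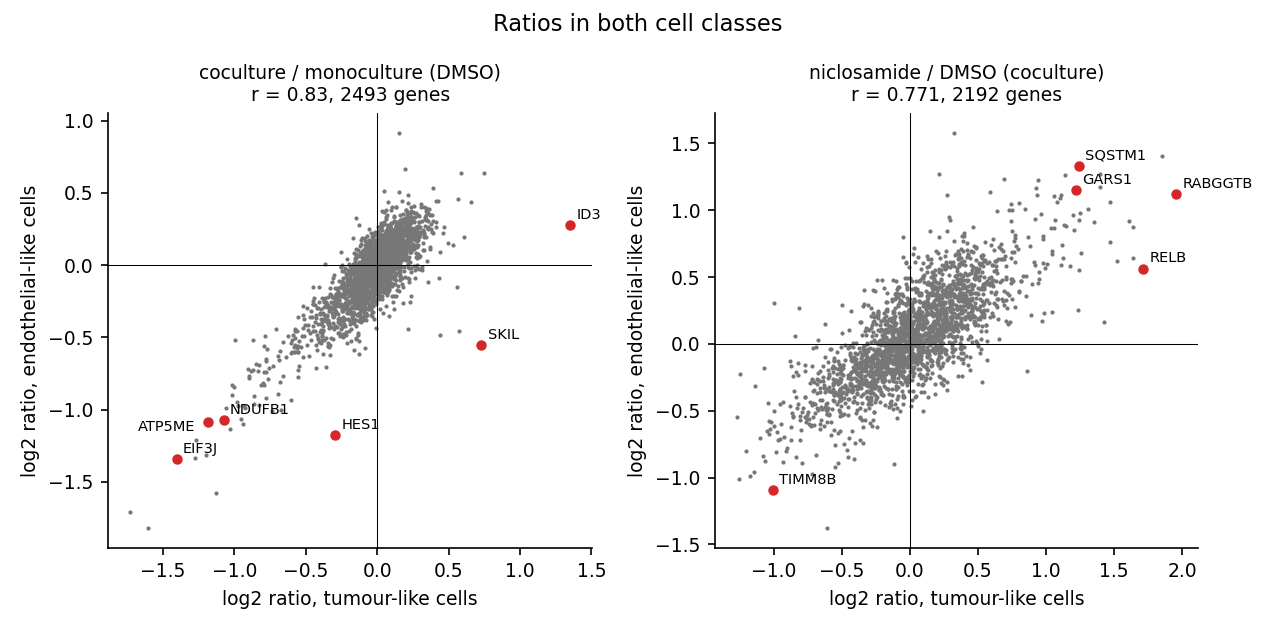
Log2 ratio of CPM in tumour-like (x axis) against endothelial-like cells (y axis) for coculture over monoculture (left, 2493 genes, r = 0.83) and niclosamide over DMSO (right, 2192 genes, r = 0.771); each point is a gene compared in both classes, and the marked genes were chosen after their values were seen. EIF3J (−1.40 and −1.34) lies low in both classes, while SKIL lies at 0.73 and −0.55.

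The comparison of the coculture libraries asks how the cell classes differed with niclosamide. In tumour-like cells, genes of the integrated stress response, a programme that the transcription factor ATF4 drives when translation is restrained, had the 3 highest ratios among the protein-coding genes compared. The noncoding SNHG12, chosen after its values were seen, stood at 76.9 against 7.1 CPM (3.44). CHAC1 (ENSG00000128965; chromosome 15, 40952962 to 40956519), which degrades glutathione, was 14.4-fold higher with niclosamide, at 27.2 against 1.89 CPM (log2 ratio 3.85, 95% interval 3.62 to 4.08). TRIB3, a pseudokinase that restrains ATF4, was 10.8-fold higher, at 114 against 10.5 CPM (3.43, 3.34 to 3.53), and DDIT3 (ENSG00000175197; chromosome 12, 57516588 to 57521737), which encodes the transcription factor CHOP, was 8.98-fold higher, at 229 against 25.5 CPM (3.17, 3.11 to 3.23). MTHFD2, a mitochondrial folate enzyme (2.11), and ASNS, asparagine synthetase (1.95), also stood higher. Of the 20 compared members of this list, 19 were higher and 14 at least 2-fold higher (median 1.28, percentile 100). Unfolded protein response genes had a median of −0.09, inside the random range (percentile 11.4), with members from −0.95 to 1.64.

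**Figure D3:**
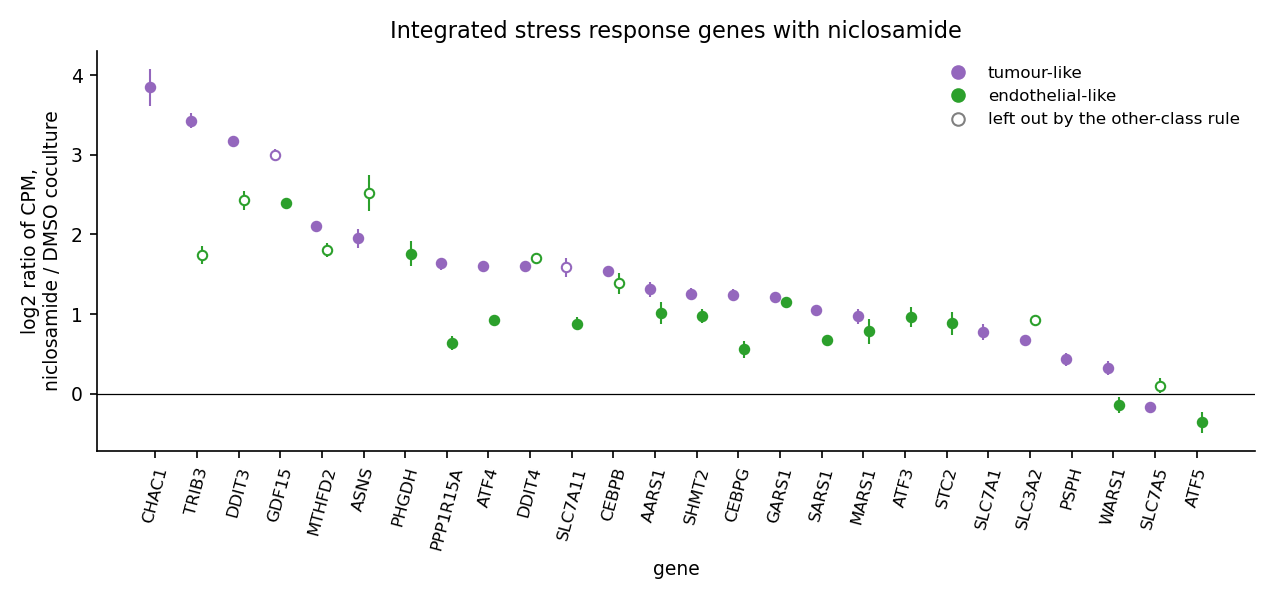
Log2 ratio of CPM, niclosamide over DMSO in coculture, for the measured integrated stress response genes in tumour-like (purple) and endothelial-like cells (green); points are the ratio of 1 library to 1 library, bars are 95% counting intervals, and open points are genes left out because RNA of the other class could give over 25% of their level. CHAC1 is highest in tumour-like cells at 3.85, and GDF15 is highest among the compared genes of endothelial-like cells at 2.40.

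Inflammatory and biosynthetic genes also stood higher in niclosamide-treated tumour-like cells. The lymphotoxin gene LTB was 7.68-fold higher (2.94, 2.88 to 3.0), at 239 against 31.1 CPM, and the interleukin gene IL1A 6.39-fold higher (2.68, 2.58 to 2.77). All 6 compared NF-kB inflammatory targets were higher and 4 were at least 2-fold higher: IL1A, IL1B (1.80), RELB (1.71) and BIRC3 (1.52), with a list median of 1.62 (percentile 100). Cholesterol synthesis genes were higher in 13 of 15 members and at least 2-fold in 5 (median 0.77, percentile 100), including MVK (1.70), HMGCS1 (1.35), IDI1 (1.20) and DHCR7 (1.07). Interferon-stimulated genes were higher in all 6 (median 0.64, percentile 99.1; IFIT2 1.46, IFIT3 0.93), and Wnt/beta-catenin targets in 3 of 4 (median 0.69, percentile 99.6; MYC 1.54, CD44 0.78). MAPK feedback targets were higher in 7 of 10 (median 0.46, percentile 99.8; DUSP5 1.29, PHLDA1 0.95) and lysosome and autophagy genes in 11 of 13 (median 0.48, percentile 99.9; SQSTM1 1.24, NEU1 1.11). The basement membrane list was higher in all 4 members (median 0.54, percentile 98.7; LAMB3 1.63, LAMA3 0.70), and genes of MYC-driven ribosome biogenesis in 14 of 19 (median 0.32, percentile 99.6; NPM1 1.02, GNL3 0.74). Outside the lists, the translation factor EIF4A2 stood at 638 against 146 CPM (2.13, 2.10 to 2.15), TAF1D, a subunit of the RNA polymerase I selectivity factor, at 512 against 135 CPM (1.92), RABGGTB, which lipidates Rab proteins, at 44.4 against 11.4 CPM (3.88-fold), the adaptor gene GRB7 at 43.1 against 9.75 CPM (2.14) and the serine protease gene PRSS22 at 84.4 against 16.8 CPM (2.33).

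Mitochondrial transcripts stood lower in the same cells. Of the 12 compared mitochondrially encoded genes 10 were lower (median −0.70, percentile 0), led by MT-ND3 (−1.27), MT-ND1 (−0.86) and MT-ND2 (−0.83). The tumour cluster with a high mitochondrial share held 37 DMSO cells and 1 niclosamide cell, doublet calls counted, and without it the median of the mitochondrially encoded genes was −0.68. Nuclear-encoded respiratory chain genes were lower in 27 of 43 (median −0.27, percentile 0.21; UQCRQ −0.95, NDUFB2 −0.86), with UQCRC2 (0.58) on the other side. COX17, the copper chaperone of cytochrome oxidase, stood at 91.9 against 209 CPM (−1.18), and HSPE1, the mitochondrial cochaperonin, at 525 against 1206 CPM (−1.20). HSPA1A, an inducible heat shock protein gene that shares reads with its copy HSPA1B, was 5.26-fold lower, at 7.17 against 37.7 CPM (−2.39, −2.51 to −2.28). HSPA1A was among the leading genes of the cluster with a high mitochondrial share, which held 37 DMSO cells and 1 niclosamide cell. The HSPA1A ratio without that cluster was not taken. Fewer such cells and a lower level in most cells thus cannot be told apart for HSPA1A. Other lower genes were TNNI2 (−1.91), the Wnt ligand gene WNT7B (−1.67), LPCAT1 (−1.66), the secretory kinase gene FAM20C (−1.46), RNF145 (−1.25), SNRPG (−1.20), CRIP1 (−1.18), TMEM14A (−1.16) and the RNA polymerase subunit POLR2L (−1.15). Metallothioneins were lower in all 4 members (median −0.68, percentile 0.08; MT1F −0.83, MT1E −0.77). TGF-beta targets were lower in 2 of 3 (median −0.52, percentile 0.98; PMEPA1 −0.59, SKIL −0.52, against TGFBI at 0.69), and G1/S genes in 14 of 24 (median −0.10, percentile 1.58; FEN1 −1.17, HELLS −0.97, PCNA −0.88). The TGF-beta median was 0.09 when genes of the other class were kept. ID3, chosen after its values were seen and left out of this comparison because endothelial RNA could give 27.4% of its level, stood at 56.1 against 429 CPM. Among 4266 genes compared, 113 were at least 2-fold higher and 32 at least 2-fold lower; 11 reached 4-fold higher and 1, HSPA1A, 4-fold lower. With the looser gene filter 517 were at least 2-fold higher and 547 lower, so the excess of higher genes was not kept once genes with few counts were admitted. Niclosamide cells formed their own tumour clusters of 1675 and 457 cells (doublet calls counted), the smaller with higher MKI67 (205 CPM), and had deeper counts per cell than DMSO cells.

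In endothelial-like cells, stress, lysosomal and redox genes stood higher with niclosamide. GDF15 (ENSG00000130513; chromosome 19, 18374731 to 18389176), a secreted stress cytokine, was 5.28-fold higher, at 485 against 91.8 CPM (log2 ratio 2.40, 95% interval 2.35 to 2.45). Of the 4 chemokine genes that stood at least 2-fold higher in coculture, CXCL1 and CXCL2 were 4.16-fold and 2.77-fold lower with niclosamide, at 46.7 against 194 CPM (−2.06, −2.13 to −1.98) and 27.1 against 75 CPM (−1.47, −1.57 to −1.37), while CCL2 (−0.82) and CXCL8 (−0.28) were lower by less than 2-fold. ALDH1A1 (ENSG00000165092; chromosome 9, 72900662 to 73080442), a retinaldehyde dehydrogenase, was 5.05-fold lower, at 17.4 against 87.7 CPM (−2.34, −2.46 to −2.22). Of 3197 genes compared, 55 were at least 2-fold higher and 23 at least 2-fold lower, but the balance depended on the processing: it was 307 and 348 with the looser gene filter, and 25 and 166 with classes set by marker UMIs, where 29 niclosamide cells were left.

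The integrated stress response list was higher in 13 of 15 compared members, at least 2-fold in 4 (median 0.89, percentile 100): GDF15, PHGDH of serine synthesis (1.76), and the tRNA synthetases GARS1 (1.15) and AARS1 (1.01). Lysosome and autophagy genes were higher in all 17 members (median 0.60, percentile 100), including the autophagy receptor SQSTM1 (1.33) and the lysosomal sialidase NEU1 (1.11). NRF2 targets were higher in all 10 (median 0.46, percentile 99.9; TXNRD1 1.27, FTL 1.05), and hypoxia targets in all 7 (median 0.63, percentile 99.9; LOX 1.14, P4HA2 0.88). Immediate early genes were higher in 7 of 8 (median 0.45, percentile 99.6; ATF3 0.96, PPP1R15A 0.64) and YAP/TEAD targets in 8 of 9 (median 0.37, percentile 98.6; GADD45A 0.86, CCN1 0.77, ANKRD1 0.47). NF-kB inflammatory targets were lower in 4 of 7 (median −0.28, percentile 1.82), with CXCL1, CXCL2 and CCL2 (−0.82) on the lower side and RELB (0.56) and ICAM1 (0.17) on the higher. Notch targets and ligands were lower in all 5 (median −0.57, percentile 0.10; GJA4 −1.25, JAG2 −0.70, EFNB2 −0.57), and p53 targets in 6 of 9 (median −0.24, percentile 2.16; TRIAP1 −0.48, TNFRSF10B −0.49), although that list holds GDF15. Further higher genes were the elastic fibre gene FBLN5 (1.82), ITGA10 (1.69), SLC17A5 (1.61), the tetraspanin gene CD9 (1.58), the ubiquitin ligase scaffold CUL4B (1.51), TNFAIP8L3 (1.47), the pentraxin gene PTX3 (1.44), PMP22 (1.39) and INHBA, an activin subunit (1.37). Further lower genes were the nonmuscle myosin gene MYH10 (−1.39), ABLIM1 (−1.38), the phosphodiesterase gene PDE4B (−1.34), NRGN (−1.34), SCARA3 (−1.29), LIMD2 (−1.24), ASRGL1 (−1.19) and MLLT11 (−1.16). Niclosamide endothelial-like cells lay almost wholly in 1 cluster (2258 of 2267, doublet calls counted), and 5 lay in the cluster with higher MKI67 that held 669 of 3105 with DMSO; in cells with low cell cycle scores the NF-kB median was 0.06. Under classes set by marker UMIs, with 29 niclosamide cells, PHGDH, PTX3, GJA4 and LOX changed direction.

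**Figure D4:**
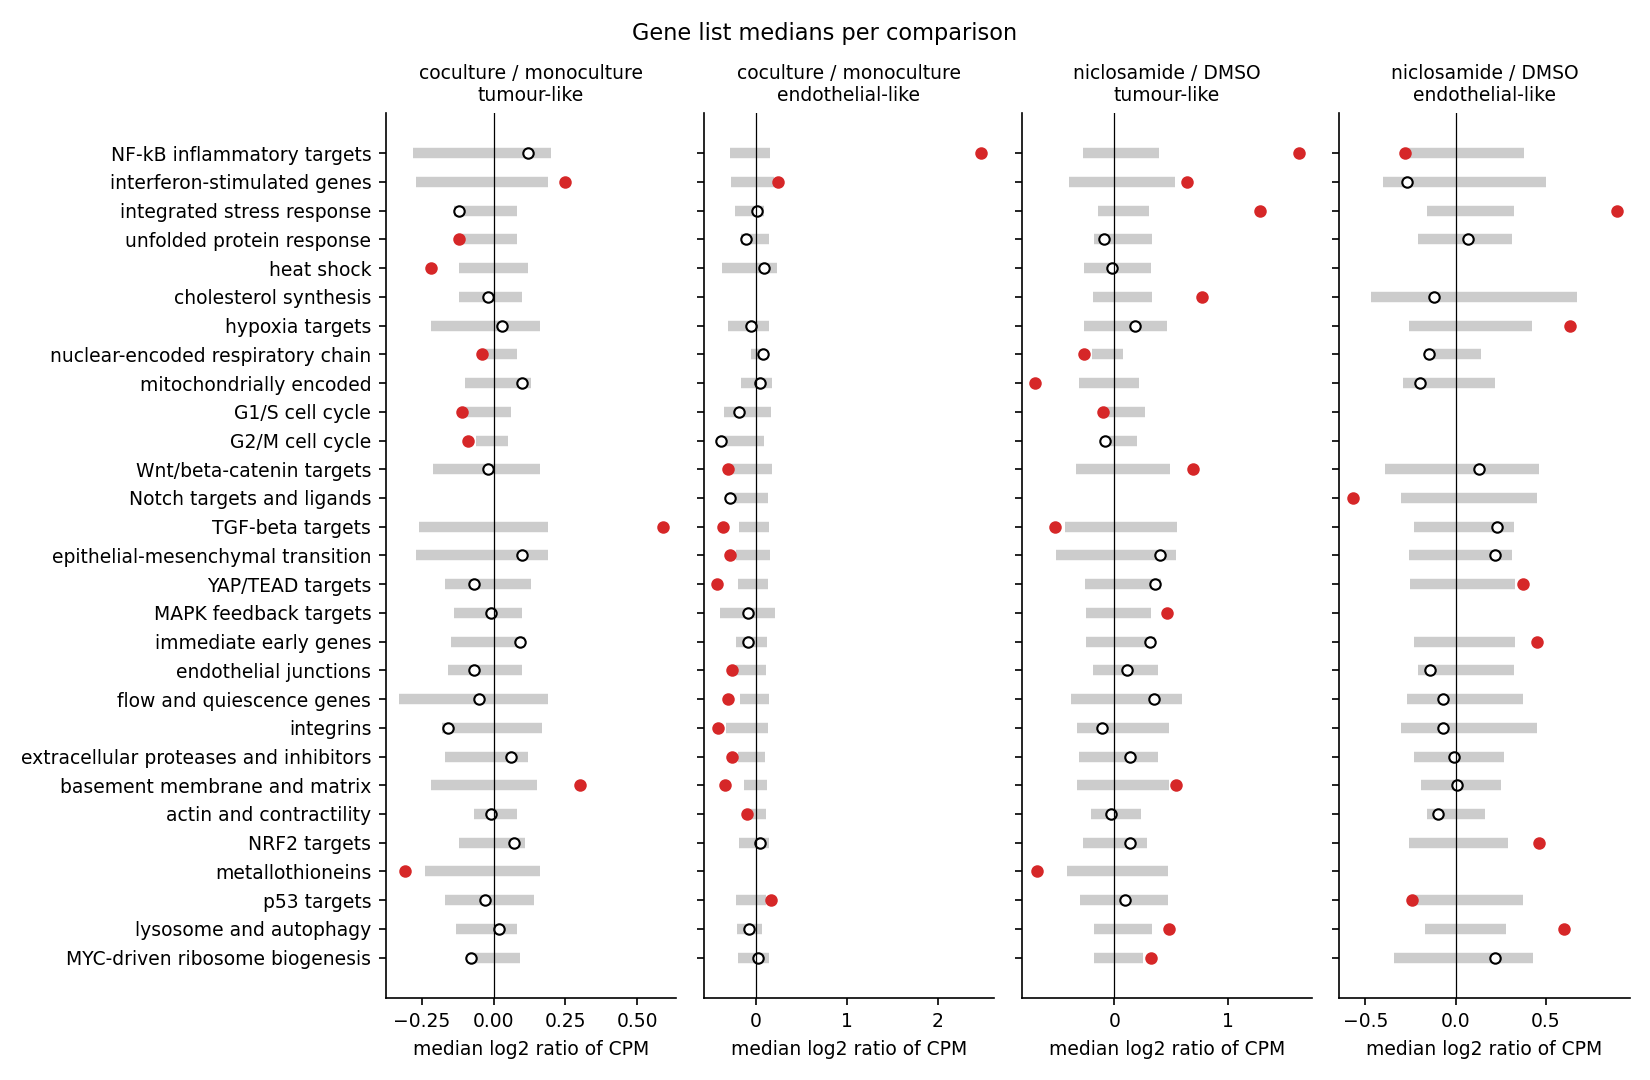
Median log2 ratio of CPM (x axis, a scale per panel) of each gene list (rows) that lay outside the central 95% of 10000 level-matched random lists in at least 1 of the 4 comparisons (panels); grey bars span the central 95% of random lists, and filled red points lie outside it. NF-kB inflammatory targets lie at 2.47 in endothelial-like cells of the coculture, and at 1.62 in tumour-like and −0.28 in endothelial-like cells with niclosamide.

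Niclosamide ratios of the cell classes had a Pearson r of 0.771 across 2192 genes. In both classes 13 genes stood at least 2-fold higher, among them SQSTM1, GARS1, AARS1, NEU1, INSIG1 and RABGGTB. The 2 genes at least 2-fold lower in both, chosen after their values were seen, were TIMM8B, a mitochondrial import chaperone (−1.01 and −1.09), and the noncoding PRR34-AS1 (−1.26 and −1.01). There were 0 genes 2-fold in opposite directions, where unrelated classes would give 0.1 and 0.2 for the 2 directions. Both classes came from the same 2 libraries and held RNA of each other, so drug and library cannot be told apart here. The last relation asks whether niclosamide ratios opposed those of coculture. Counting error in the shared coculture DMSO library gives a negative relation. When libraries differing by counting error alone were simulated, r was −0.53 in tumour-like and −0.465 in endothelial-like cells. Their covariance was only −0.0005 and −0.0009, against measured values of 0.0155 and 0.0033. The simulated r is thus not the amount by which counting error lowers the measured r. Variation of the shared library beyond counting error was not simulated, and a split of its cells does not remove it. The measured r was 0.175 across 3962 genes in tumour-like and 0.03 across 3013 genes in endothelial-like cells. It was 0.18 and 0.038 when the cells of the shared library were split between the comparisons. With a looser gene filter both correlations were negative. Of the 8 genes at least 2-fold higher in cocultured endothelial-like cells, 3 were at least 2-fold lower with niclosamide: CXCL1, CXCL2 and TNFSF10 (20.7 against 44.5 CPM, −1.10). The shared library by itself favours this direction, and no count without change was simulated for it. CCL2 lay at 509 CPM with niclosamide, between 162 CPM in monoculture and 897 CPM in coculture with DMSO.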

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

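The tests of the NF-kB pattern, and those of depth, of tumour RNA and of per-cell shares after subtraction for the stress response, were chosen only after the result was seen; the others were set before. For 3 gene lists the median lay outside the central 95% of random lists in both cell classes, on opposite sides of no change, under the same contrast, and with 1 library per group none of these differences was tested. TGF-beta targets in coculture had a median of 0.59 in tumour-like and −0.36 in endothelial-like cells, a difference of 0.95; SKIL was the 1 member compared in both (0.73 and −0.55). The basement membrane list in coculture had 0.30 and −0.34, a difference of 0.64, with 0 members compared in both. NF-kB targets with niclosamide had 1.62 and −0.28, a difference of 1.90, but the lists held different members, and the 2 compared in both, RELB (1.71 and 0.56) and NFKBIA (0.19 and 0.33), stood higher in each class.

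NF-kB targets stood higher in endothelial-like cells of the coculture. RNA of tumour cells could give a median of 2.6% of the gain in CPM over the 7 members at least 2-fold higher (1.4% to 32.2%, the highest being NFKBIA, which the limit on other-class RNA left out of the comparison), which argues against it as the source. In cells with low cell cycle scores the list median was 2.34. This argues against a different mix of cycling cells as far as the scores mark cycling cells, since tumour RNA was not taken out of them. Of their genes in endothelial-like cells, 26 for G2/M and 13 for G1/S were left out of this comparison for other-class RNA, and 4 and 4 were compared. Immediate early genes outside the list had a median of −0.13 over 10 members (−0.93 to 0.13), which argues against cell handling that raised such genes. A response of endothelial cells to tumour cells may underlie the pattern, as a hypothesis only, since culture form and library cannot be told apart with 1 library each.

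Lists of matrix, integrin, junction, protease, actin and YAP/TEAD genes stood lower in endothelial-like cells of the coculture, where longer transcripts also stood lower, as they did in tumour-like cells (Spearman rho −0.41 and −0.18). Random lists were then matched on transcript length as well as level, in 5 bins each, which leaves differences in length within a bin. Against these, 9 of the 10 lists stayed at or under percentile 2.5, the exception being endothelial junctions at 2.77. This argues against length as the whole cause, but lists share members such as CCN2 and COL4A2, so the 10 are not separate results. In cells with low cell cycle scores 10 of 10 lists kept at least 50% of their median, which argues against a different mix of cycling cells. The 41 members compared in both classes had a median of −0.01 in tumour-like cells (95% order interval −0.12 to 0.09) and −0.18 in endothelial-like cells; that interval reaches past −0.088, 50% of the endothelial value, so a library difference shared by both classes cannot be told apart from a difference of endothelial cells alone. An effect of coculture on endothelial cells stays open.

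Integrated stress response genes stood higher with niclosamide in both classes. With every cell thinned to the same depth the tumour list median was 1.41 over 20 members (−0.23 to 4.07). CPM are already relative to the class total, and random thinning within a cell keeps its expected composition. The thinned median could thus hardly have come out otherwise, and it decides nothing about the deeper counts of tumour-like cells. After RNA of tumour cells was subtracted the endothelial list median was 0.96 over 20 members, which argues against tumour RNA in endothelial-like barcodes. In thinned cells 84.9% of tumour-like niclosamide cells lay above the 95th percentile of DMSO cells. The share was 81.9% when RNA of endothelial cells was subtracted from niclosamide cells alone. These shares argue against a small subset of tumour-like cells. Subtraction in both libraries also gave 84.9%, but it took means of 0.75 (DMSO) and 1.57 (niclosamide) UMIs per cell. These differ by less than a whole UMI, so that value could not have changed and adds nothing. In endothelial-like cells the share was 67.7%, but 46.1% after RNA of tumour cells was subtracted in both libraries. It was 35% when tumour RNA was subtracted from niclosamide cells alone, which lowers the share by construction. A subset and most cells thus cannot be told apart in endothelial-like cells. A drug response of most tumour-like cells may underlie the pattern in that class, as a hypothesis only, since drug and library cannot be told apart with 1 library each.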

How the results depend on the processing

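The alternatives of subtracting other-class RNA for named genes and lists, of leaving out or adding clusters or mixed barcodes, and of thinning for lists were chosen only after the result was seen. Over the 8 alternatives run for named genes, 1337 values stayed within their counting interval, 571 moved beyond it with the direction kept, and 4 changed direction; over the 7 run for lists, 822 medians moved by at most 0.1, 90 by more, and 5 changed direction. Counts below are genes higher, then lower; the cause was not tested except that filters and fold thresholds admit fewer or more genes by construction. At 200 UMIs and 50 CPM, counts were 5 and 17 for coculture in endothelial-like, 66 and 19 for niclosamide in tumour-like and 25 and 11 in endothelial-like cells. At 10 UMIs with no CPM minimum they were 113 and 270 for coculture in tumour-like and 103 and 197 in endothelial-like cells, and 517 and 547 and 307 and 348 for niclosamide; r was then −0.067 for drug ratios against coculture ratios, tumour cells, and −0.124 for drug ratios against coculture ratios, endothelial cells. At 1.5-fold they were 12 and 99, 18 and 138, 425 and 228, and 293 and 153 in the same order. At 3-fold they were 0 and 4 for coculture in tumour-like cells, with 2 lower in endothelial-like cells, and 28 and 4 and 5 and 2 for niclosamide. Classes by marker UMIs, a rule that left out most endothelial-like cells of each library, gave tumour-like shares of 52.8%, 67.9% and 98.4%. Under it 14 genes were higher in endothelial-like cells of the coculture. With niclosamide 29 endothelial-like cells remained, with 25 genes higher and 166 lower. PHGDH was then −1.55, PTX3 −0.40, GJA4 0.19 and LOX −0.17. With other-class genes kept, 7 genes were higher in coculture in tumour-like and 37 lower with niclosamide in endothelial-like cells, and the TGF-beta median with niclosamide in tumour-like cells was 0.09. With other-class RNA subtracted, 5 and 15 genes were higher in coculture in tumour-like and endothelial-like cells, and 59 lower with niclosamide in endothelial-like cells. With low cell cycle scores only, 4 genes were higher in coculture in tumour-like and 36 lower with niclosamide in endothelial-like cells; list medians were −0.01 for interferon-stimulated genes and 0.00 for G2/M genes in coculture in tumour-like cells, 0.06 for G1/S genes with niclosamide in tumour-like cells and 0.06 for NF-kB targets with niclosamide in endothelial-like cells; for the cycle lists the selection itself takes away differences, so these values say nothing about their direction. Endothelial-like cells had the lower depth, at a median of 12561 to 14521.5 UMIs against 34434 to 48323 in tumour-like cells. No paired analysis was possible because each group had 1 library.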

Other observations

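The test of host genes with other-class RNA subtracted was chosen only after the result was seen, as were the genes given below outside the lists. Several gene groups not described so far stayed inside the random range. In endothelial-like cells of the coculture, the leukocyte adhesion list had ICAM1 (3.29) as its 1 higher member of 6, with MCAM (−0.44), ALCAM (−0.32) and PODXL (−0.24) lower (median −0.18, percentile 10.6). In niclosamide-treated tumour-like cells, STAT3 targets were higher in all 7 members (median 0.36, percentile 96.1; PIM1 1.76, LCN2 0.89), and glycolysis genes in 8 of 12 (median 0.23, percentile 96.6; SLC16A3 0.58, PKM 0.48). Epithelial junction genes were higher in 8 of 10 (median 0.24, percentile 90.8; PKP2 0.64, PKP3 0.56). In endothelial-like cells with niclosamide, angiogenic sprouting genes went both ways (median 0.20, percentile 80.8), with CXCR4, a chemokine receptor (1.40), and ESM1 (0.89) higher and APLN (−0.64) and ROBO4 (−0.57) lower; APLN had also stood lower in coculture (−1.04). BMP/ID targets were lower in all 4 members there (median −0.35, percentile 3.72; ID3 −0.93, BMP4 −0.55). In tumour-like cells ID1 stood at 617, 963 and 564 CPM in the monoculture, coculture DMSO and niclosamide libraries.

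Cells with high interferon-stimulated genes (IFIT1, IFIT2, IFIT3 and ISG15) formed a tumour-like cluster of 135 cells, 41 in monoculture, 45 in coculture with DMSO and 49 with niclosamide. A cluster of 85 cells led by IL1RL1, PLAT and RGS5 could not be named from the markers. Mitochondrially encoded genes went both ways in coculture: MT-ND3 had −0.96 in tumour-like and −1.06 in endothelial-like cells and MT-ND6 −0.85 and −0.69, while MT-CYB had 0.20 and 0.16. Among the genes lower in coculture in both classes, SNHG25 stood at 72.6, 23.9 and 19.6 CPM in tumour-like cells of the monoculture, coculture DMSO and niclosamide libraries, and RPS29 at 3933, 1624 and 1213 CPM.

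EIF4A2, TAF1D and RABGGTB, all higher with niclosamide in tumour-like cells, hold snoRNA genes in their introns, and a hypothesis was that such host genes may stand higher together. The other 75 host genes compared in tumour-like cells, without ribosomal protein genes, had a median of 0.20 (percentile 99.7 of matched random lists). Of these 47 were higher and 7 at least 2-fold higher, which goes with the hypothesis. Apart from the protein-coding CCNB1IP1 (1.47), those 7 were noncoding genes such as SNHG12 (3.44) and EPB41L4A-AS1 (2.19). The next protein-coding hosts were EEF2 and KPNA4 (both 0.83), and the noncoding SNHG30 (−0.54) and SNHG10 (−0.46) stood lower. No median was taken for protein-coding hosts alone. In endothelial-like cells 44 such genes had a median of 0.01 (percentile 39.8), with 22 higher and 2 at least 2-fold higher. That percentile lay under the limit set beforehand as counting against the hypothesis, which argues against it for these 44 genes. However, 25 measured host genes were left out for other-class RNA, 1 of them at least 2-fold higher, EPB41L4A-AS1. With other-class RNA subtracted in their place, 63 had a median of 0.07 (percentile 89.6), with 36 higher. This lies close to the limit, so the hypothesis stays open for the host genes left out.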
